A study of Homo sapiens with 4 samples.

How the data were processed

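RNA was measured by sequencing in RKO cells, an established human colorectal cancer line, either wild type (WT) or overexpressing ZCCHC7 (OE). The 4 libraries were 1 input and 1 immunoprecipitate (IP) for each genotype, so every group held 1 library and no test between the genotypes was possible. The sources disagreed on the antibody. The sample characteristics named ZCCHC7, while the labels' protocols described beads coated with an antibody against SRSF1 and then an antibody against m6A. The libraries are therefore called input and IP here, with no statement on the protein or mark that was pulled down.

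Peaks were called by the authors with MACS 2.1.0.20150420, once per genotype on 1 IP library against its input, per the file headers. The headers gave a p cutoff of 0.005, kept duplicate tags, scaled the larger library to the smaller and set an effective genome size of 209714707 bases. That size is far below the length of the human genome, and it set the background, and so the fold and p, at 14 WT peaks and 2 OE peaks. The submitters' processing notes also named FastQC 0.11.5 and HOMER. The aligner and the genome build were not given in the sources used here. The names of the alignments in the headers carried a mark that reads as unique, which the headers did not explain. The deposited peak lists held, per summit, a pileup signal on the scale of the smaller library, a fold ratio of IP over local background, and −log10 p and q values, all as the authors' peak caller wrote them. The deposited splicing tables held inclusion and skipping junction counts per event, with the authors' p-value, FDR and inclusion level difference, in 5 event classes. Each count cell held 2 values per genotype, and no source said which library each value came from. Single-value and stratified comparisons set first values against first and second against second. They thus assume the same order of libraries in both genotypes. The first sample of each table was taken as OE and the second as WT from the name of the comparison alone.

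Whole IP tags at each summit were recovered by dividing the authors' pileup by the ratio of input to IP tags. All 67 WT and 39 OE summits gave a whole number within 0.1. Local input background was computed from pileup and fold, and is whole where a window at the summit set it. Depth-scaled tags are tags per 1000000 IP tags of the library. Ratios of tags carried an exact 95% binomial interval and single counts an exact Poisson interval. Both cover counting error only, since sequenced tags without molecular identifiers are not independent molecules. For summits shared by both lists, IP and input tags of WT and OE were compared by an exact two-sided conditional test whose expected odds came from the library totals, where both input values were whole within 0.01. Peaks with several summits were represented by the summit with the smallest p, except that a shared OE peak with several summits was set beside WT at its summit nearest to the WT one.

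Peaks were placed against the deposited gene annotation in 6 classes, taken in order from the mitochondrial genome and unplaced scaffolds to exons, introns and positions outside genes. The lists carried no annotation of their own, so the deposited annotation was the only one used. Of 36016 gene symbols found once in both that annotation and RefSeq on GRCh38.p14, 99.9% overlapped on the same chromosome. Coordinates are those of the deposited files. Peaks were shared when they overlapped by at least 1 base. Class shares carried exact Clopper-Pearson 95% intervals, and Fisher's exact test (two-sided) set the classes of the lists against each other with Benjamini-Hochberg adjustment.

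For splicing, the 2 values of a genotype were added, because the design had assumed 1 library per genotype in these tables. Events needed at least 10 inclusion plus skipping counts in each genotype. Fisher's exact test (two-sided) was run on the inclusion and skipping counts of each event, with Benjamini-Hochberg adjustment over all classes and a threshold of 0.05. It compares these libraries, not the conditions. Inclusion levels were corrected for the lengths of the inclusion and skipping forms, whereas the tested counts were not. On simulated counts for the 32 tested events, with 16 changed in each of 100 simulations, the test recovered 11.1% of events changed by 4-fold odds and 73.8% of those changed by 16-fold odds. Of the unchanged events, 0% and 0.688% were called. Those simulations left out the difference between the first and second values. With each value keeping its own depth and inclusion rate and no difference between genotypes within either, 100 simulations of the 32 events gave a mean of 3.27 calls on the added counts (0 to 9) and 0 in the stratified test, which could reach an unadjusted p under 0.05 in 13 of the 32 events.

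Most named items followed a rule set before the data were examined. It took the authors' significant events, up to 5 tested events per class and direction by Fisher p, the 10 highest peaks with a gene in each list, up to 20 genes with a peak in both lists, genes with a peak and a tested event, members of 21 gene lists with a peak or event, and ZCCHC7 and SRSF1. The lists covered cofactors and core of the RNA exosome, SR and hnRNP proteins, core spliceosome, other splicing regulators, ribosome biogenesis, nonsense-mediated decay, m6A machinery, colorectal cancer drivers, kinase signalling, apoptosis and cell cycle, abundant short noncoding RNAs, long noncoding and snoRNA hosts, markers of other cell types, ribosomal proteins, mitochondrially encoded genes, histones, snoRNAs, proteasome subunits and translation factors. Some named genes fell outside the rule, among them RBM19, KDM5A, ZCRB1, UBXN4, TIMP3, SSRP1, PHGDH, HMGN1 and INTS11. Alternatives changed the count minimum, the adjustment, the scaling of counts, the peak threshold and the overlap rule. Others, among them single values and a stratified exact test, were chosen after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.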

Results

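The data covered RKO colorectal cancer cells, wild type (WT) or overexpressing ZCCHC7 (OE), a zinc-knuckle protein known as a cofactor of the nuclear RNA exosome. The title of the study asks how ZCCHC7 acts in colorectal cancer and on which targets. Each genotype had 1 input and 1 IP library, with no replicates. The peak headers gave 896288 WT IP tags with 207641 input tags, and 2725742 OE IP tags with 396820 input tags, so the OE IP library was 3.04 times as deep as the WT one. The splicing tables held 3833 junction counts for WT and 2432 for OE over 471 events. Neither ZCCHC7 nor SRSF1, the splicing factor named in the protocol, had a peak or a listed event, so the overexpression itself could not be checked from these values.

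The first comparison asked which RNAs were enriched in the IP of each genotype. SAE1, which encodes a subunit of the SUMO-activating enzyme, and its processed pseudogene SAE1P1 stood out in both lists: outside the mitochondrial genome, the most IP tags lay at SAE1P1 and then at exon 1 of SAE1. SAE1 (ENSG00000142230, chromosome 19) had 8 peaks in each list, at exons 1 to 7 and exon 9 of transcript SAE1-201. In OE the peaks at exons 5 and 6 did not reach q under 0.05. In the authors' lists their fold over background ran from 10.7 to 64.5 in WT and from 3.19 to 16.2 in OE. SAE1P1, listed as AP003040.1 (ENSG00000213184, chromosome 11, 123017638 to 123018661), reached a fold of 137.8 in WT and 11.4 in OE.

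Tag counts were nearly equal in both libraries at 6 of the 8 SAE1 exons with a peak, although the depths differed. Exon 1 (47130863 to 47131028) had 1668 tags in WT and 1587 in OE, exon 7 (47197233 to 47197377) had 1072 and 1044, and exon 9 had 806 and 786. The OE over WT tag ratio was 0.951 to 0.996 at these 6 exons (1 to 4, 7 and 9) and 0.712 at exons 5 and 6, which had 73 and 52 tags in WT. SAE1P1 had 10701 tags in WT and 9661 in OE. Summed over the 8 summits, SAE1 had 5437 tags in WT and 5216 in OE. Scaled to IP depth, OE stood at 0.315 times WT (95% interval 0.304 to 0.328), and SAE1P1 at 0.297 times (0.289 to 0.305). Exon 8, 70 bases long, carried no peak in either list. The last peak ended 155 bases into the 940-base 3' UTR (47209252 to 47210191) in both lists, and the other 785 bases had none. SAE1 was in none of the splicing tables. SAE1P1 is a copy of SAE1, so the split of tags between them is uncertain.

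**Figure D1:**
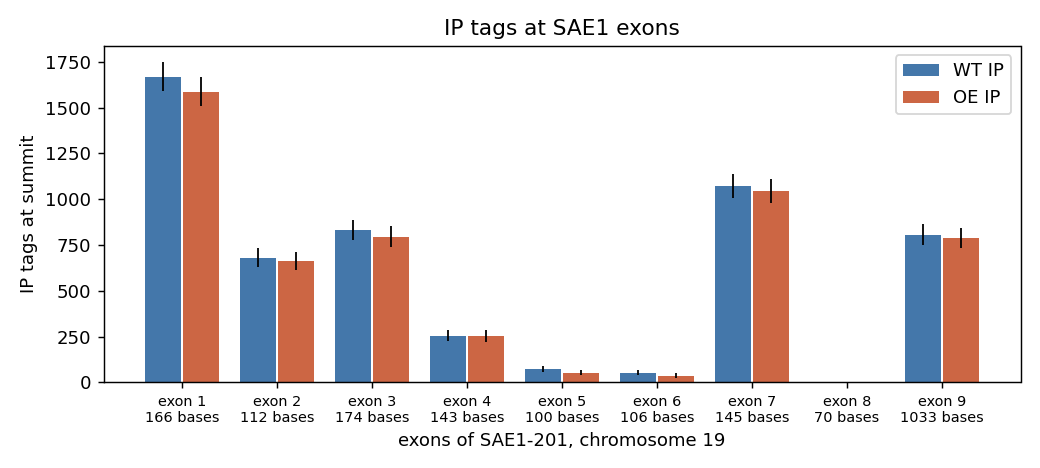
IP tags at the summit of the peak over each exon of SAE1-201 in WT and OE; bars are tag counts and lines exact 95% Poisson intervals. The counts of both libraries lie close together at exons 1 to 4, 7 and 9, stand lower in OE at exon 5 (73 and 52) and exon 6 (52 and 37), and exon 8 has no peak.

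The other 7 shared peaks lay at RMRP, RAD21, EEF1A1, mitochondrial genes and pseudogenes, and 2 positions outside genes. Of these, the RMRP peak alone had q under 0.05 in both lists, and the others in 1 list each. RMRP, the RNA of the RNase MRP ribonucleoprotein (chromosome 9, 35657605 to 35658010 in OE), had 106 tags in WT and 89 in OE, which is 0.276 times WT in OE after depth scaling (0.206 to 0.369). RAD21, a cohesin subunit, had an exon peak on chromosome 8 with 68 and 60 tags, 0.29 times after scaling (0.2016 to 0.417). This peak overlapped coding and 5' UTR features pooled over all RAD21 transcripts, which does not place it within the mRNA. EEF1A1, a translation elongation factor, had a peak in a 5' UTR exon on chromosome 6 with 36 and 138 tags, and its ratio of 1.26 (0.868 to 1.87) was not distinguished from 1. The mitochondrial pseudogenes MTCO1P12 and MTCO2P12 on chromosome 1 had 48 and 222 tags, a ratio of 1.52 (1.11 to 2.12). Set against input the genotypes were not distinguished at RMRP, RAD21 or these pseudogenes: IP over input was 12.3 in WT and 13 in OE at RMRP, 5.25 and 4.37 at RAD21 (exact adjusted p = 1 for both) and 5.56 and 32.3 at the pseudogenes (exact adjusted p = 0.232), from 1 to 3 input tags. The WT mitochondrial peak over MT-ND4L and MT-ND4 had 165 tags, and the nearest of the 8 summits of the OE peak, which ran over 3651 bases from MT-CO2 to MT-ND4, had 775, a ratio of 1.54 (1.3 to 1.84). The peaks outside genes, named after their values were seen, lay on chromosome 12 (66057457 to 66057825 in WT) with 197 and 147 tags, a ratio of 0.245 (0.197 to 0.305), and on chromosome 4 (49092641 to 49092974 in WT) with 35 and 84, a ratio of 0.789 (0.526 to 1.21). Of the 16 shared peaks, 12 had fewer depth-scaled tags in OE beyond counting error, 2 had more and 2 were not distinguished. Of the 12, 9 were the SAE1 exons and SAE1P1, and the other 7 shared peaks split into 3 lower, 2 higher and 2 not distinguished. The 2 higher were the mitochondrial peak and the mitochondrial pseudogenes on chromosome 1, which need not be independent of each other.

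**Figure D2:**
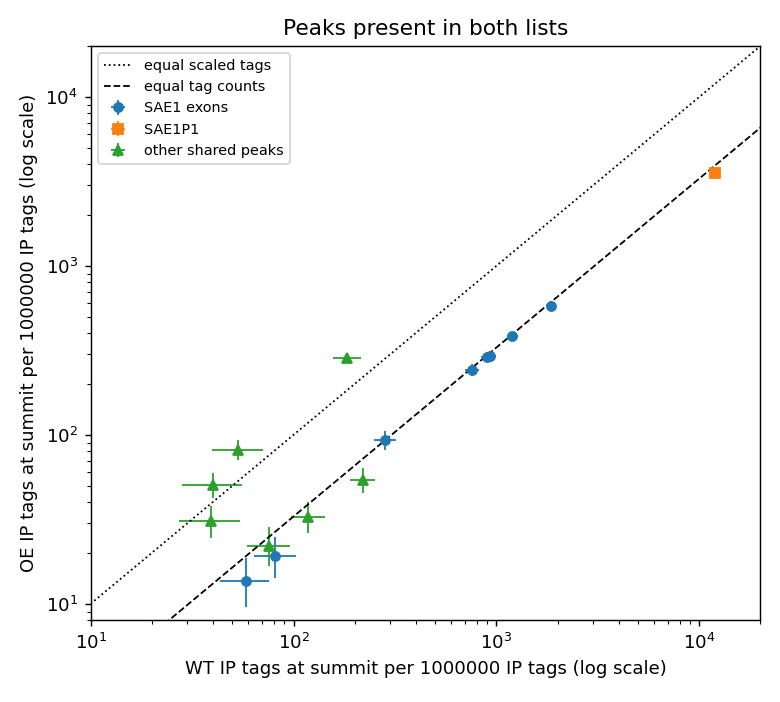
IP tags per 1000000 IP tags at the summits of the 16 shared peaks, WT against OE, both axes logarithmic, with exact 95% Poisson intervals. SAE1 exons and SAE1P1 lie near the dashed line of equal tag counts, 3.04 times below the dotted line of equal scaled tags.

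The WT list was the longer one, although its IP library was the shallower. The peak caller scaled each IP library down to its input, so peak numbers need not follow IP depth. The WT list held 57 peaks and the OE list 30, a ratio of 1.9 (exact 95% interval 1.2 to 3.06). That interval treats peaks as independent, although several were neighbours and each list came from 1 IP library. At q under 0.05, a threshold chosen after the data were seen, the lists held 23 and 15 peaks, a ratio of 1.53. Of the OE peaks, 16 (53.3%, 34.3 to 71.7) overlapped a WT peak, 14 were in the OE list alone and 41 in the WT list alone. Without the peaks at SAE1 and SAE1P1 the shared part was 7 of 21 OE peaks, or 33.3% (14.6 to 57). The lists touched 26 genes in WT and 23 in OE, with 10 in both: SAE1, AP003040.1, EEF1A1, RAD21, RMRP, MT-ND4, MT-ND4L, MTCO1P12, MTCO2P12 and AL669831.3, which spans the pseudogene cluster on chromosome 1. The median fold in the authors' lists was 3.85 in WT (range 1.68 to 137.8) and 4.85 in OE (2.18 to 16.7). Part of these folds, those of SAE1 exons 4 to 6 in WT included, rested on a background set by the genome size given to the peak caller. This background was 0.224 input tags in WT and 0.448 in OE. It applied to 14 WT peaks and 2 OE peaks, so it bears on the peak numbers too.

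Several genes had a peak in 1 list alone. In WT, DEAF1, a transcription factor, had a peak with 38 tags over a coding exon on chromosome 11 (674536 to 674791). ANKDD1A on chromosome 15 had 2 neighbouring peaks with 237 and 184 tags, the first also over an exon of AC103691.1. Small WT peaks lay over coding exons of RBM19, a ribosome biogenesis factor, with 22 tags, the histone demethylase gene KDM5A with 9, ZCRB1 with 16 and UBXN4 with 24. None of these small peaks had q under 0.05. The WT peak in MT-RNR2, the mitochondrial large ribosomal RNA, had 13245 tags with a fold of 2.22 only. In OE, TIMP3, an inhibitor of matrix metalloproteinases, had a peak with 59 tags over its last coding part and 3' UTR on chromosome 22 (32859142 to 32859414), inside SYN3. The mitochondrial pseudogenes MTND1P23 and MTATP6P1 had 103 and 96 tags. A peak absent from a list of this depth was not called there, which does not show that the RNA was absent.

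Protein-coding exons held 15 of 57 WT peaks (26.3%, 15.5 to 39.7) and 11 of 30 OE peaks (36.7%, 19.9 to 56.1). Positions outside genes held 21 WT peaks (36.8%, 24.4 to 50.7) and 11 OE peaks (36.7%, 19.9 to 56.1). Introns held 7 WT peaks and 1 OE peak, and unplaced scaffolds 8 and 1. Counted by peak, none of the 6 classes differed between the lists by Fisher's exact test, with a smallest p of 0.155 for scaffolds (adjusted p = 0.502). Counted by summit, an alternative chosen after the data were seen, introns (16 of 67 in WT, 2 of 39 in OE) and the mitochondrial genome (2 and 8, the 8 in 1 peak) differed (exact adjusted p = 0.0452 and 0.0284). Summits of 1 peak are not independent. The 2 neighbouring ANKDD1A peaks in WT held 4 summits each, most of them in introns. The test compares these lists, not the conditions.

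**Figure D3:**
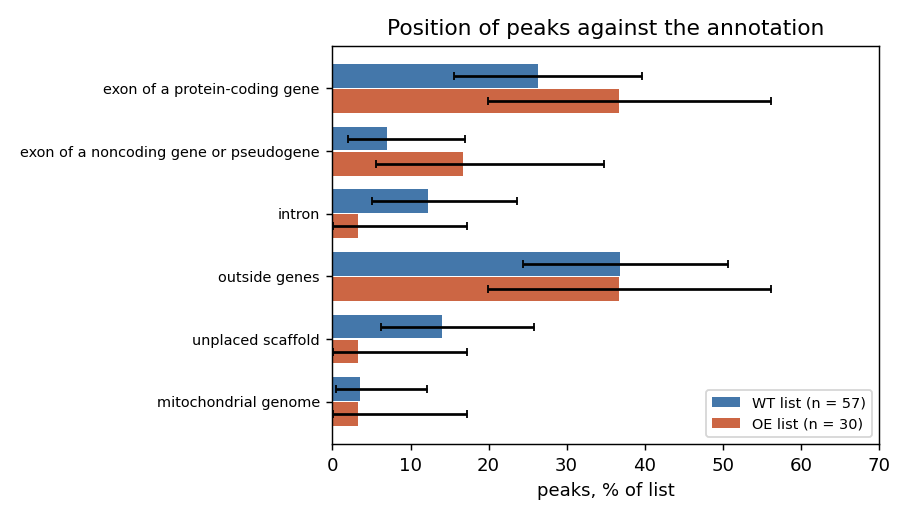
Share of peaks in each annotation class, in percent of the 57 WT and 30 OE peaks; lines are exact 95% intervals. Intervals of both lists overlap in every class, and positions outside genes hold 36.8% and 36.7%.

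The second comparison asked whether splicing differed between OE and WT. Retained introns held most calls, made on the added counts of the 2 values. On these counts intron inclusion was higher in OE than in WT in NCL, which encodes nucleolin, and RPS15 and RPLP1 of the ribosome. The same held for DBNL, an actin-binding protein, SRA1, PTMA (prothymosin alpha) and SSRP1, a subunit of the histone chaperone FACT. PTMA had 2 events at the same coordinates with the same inclusion counts. MPRIP, a partner of myosin phosphatase, was the only skipped-exon call. Of 471 events, 32 in 25 genes reached 10 counts in each genotype, and 9 events in 8 genes passed Fisher's exact test, all with higher inclusion in OE. At an unadjusted p under 0.05 there were 13. These calls came from the added values of each genotype, which differed among themselves. An exact test stratified by value kept RPS15 alone (adjusted p = 0.0156). It assumes the same order of libraries in both genotypes, which no source gave. Even before adjustment it could not have reached 0.05 in NCL, RPLP1, DBNL, SRA1 or SSRP1. There the counts within each value left too little to compare. In DBNL, SRA1 and SSRP1 levels were equal in the 1 value with counts in both genotypes. They were 0% in DBNL and 100% in SRA1 and SSRP1. In NCL and RPLP1 OE stood higher in 1 value. The smallest p that the stratified exact test could give was 0.000236 and 0.0061 in the 2 PTMA events and 0.00824 in MPRIP. With the other events as observed, 0.0061 and 0.00824 would not pass adjustment. Among the lost calls the stratified outcome thus bears on 1 PTMA event only. Simulations with no difference between genotypes within either value still gave a mean of 3.27 calls on added counts, and 9 in 1 of 100 simulations. The test compares these libraries, not the conditions.

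Coordinates of retained-intron events span the intron and both flanking exons, and those of 3' site events the longer exon. NCL had 7 inclusion and 4 skipping counts in OE against 0 and 30 in WT. Its event lay on chromosome 2 (231458266 to 231459125, Fisher's exact adjusted p = 0.00047). RPS15 had 17 and 4 counts in OE against 3 and 14 in WT on chromosome 19 (1438807 to 1440253; exact adjusted p = 0.00256), and its length-corrected inclusion level was 33.2% against 2.44%. RPLP1 had 4 and 19 counts against 0 and 151 (exact adjusted p = 0.00256), a difference in level of 1.93 percentage points. DBNL had 9 and 3 against 0 and 10, and SRA1 14 and 0 against 4 and 6 (exact adjusted p = 0.00296 and 0.00832). The long MPRIP exon on chromosome 17 had 32 and 4 against 4 and 8 (exact adjusted p = 0.00296). Retained-intron levels in TBCA and DRAP1 were lower in OE by value, with exact adjusted p of 0.648 and 0.665.

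Among alternative splice sites no event passed. SMTN, a smooth muscle cytoskeletal protein, had 5 inclusion counts of 11 in OE and 0 of 10 in WT at a 3' site (exact adjusted p = 0.102). FBL, the nucleolar methyltransferase fibrillarin, had an inclusion level of 81.8% in OE and 94.7% in WT at a 5' site (exact adjusted p = 0.103). PTMS, RPS3, PTMA and TNNT1 at 3' sites and RPL10A at a 5' site had exact adjusted p of 0.142 or more. Among skipped exons, DVL3 of the Wnt pathway had 0 inclusion counts of 10 in OE and 5 of 11 in WT (exact adjusted p = 0.102). NDUFB2, TNNT1, DEAF1, EEF1D, LRRFIP1 and SRRM2 had exact adjusted p of 0.382 or more. No mutually exclusive exon event reached the minimum.

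Over the 32 tested events inclusion was higher in OE in 25 (78.1%, 60 to 90.7) and lower in 7. The median difference was 10.3 percentage points (quartiles 0.855 and 26.8). The interval treats events as independent. Over all listed events, first and second values held 3016 and 817 counts in WT and 913 and 1519 in OE. Inclusion was 26.7% and 45.7% of these in WT and 37.7% and 80.3% in OE. Added counts therefore weighed the second value, with its higher inclusion over all classes together, more in OE. Retained introns were higher in 15 of 17 events, with a median of 14 points, but with the first values alone 0 of 5 were higher, 1 was lower and 4 were equal, and with the second values alone 2 of 3 were higher. Skipped exons were higher in 5 of 8, 3' sites in 4 of 5 and 5' sites in 1 of 2. Over all classes, 5 of 15 events with the first values alone were higher, 3 lower and 7 equal, and with the second values alone 3 of 5 were higher.

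The authors' significant lists held 1 event. In the authors' deposited table, an alternative 3' splice site of RPS9, a small-subunit ribosomal protein gene (chromosome 19, 54206553 to 54207647), had a p of 1.59e-09, an FDR of 9.06e-08 and an inclusion difference of 0.986 as a fraction, OE minus WT. Its counts were 6 inclusion and 0 skipping in OE and 1 and 12 in WT, so OE stayed under the minimum of 10. The authors' deposited table gave p under 0.05 without passing FDR to PHGDH, HMGN1 and INTS11 among retained introns and SMTN among 3' sites, at another SMTN site (31095852 to 31096897) than the one described above. None of the events called above on added counts had p under 0.05 in the authors' deposited table. The smallest authors' p among them was 0.222, at RPS15.

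Ribosomal protein genes were the best represented list, with 47 events in 29 genes. Of their 6 tested events, in RPS3, RPS15, RPL10A and RPL28, 1 passed, that of RPS15, and the same 1 when adjusted over the list alone. RPLP1 was outside that list. In the ribosome biogenesis list NCL passed, FBL did not and PES1 was under the minimum, and 2 events, those of NCL and FBL, passed when adjusted over the list alone. Among translation factors, 14 events lay in EEF1A1, EEF1D, EIF2B4, EIF2B5, EIF3B, EIF3E, EIF4G2 and EIF6, and the tested EEF1D exon did not pass. The core spliceosome list had events in DDX17, EFTUD2, RBM39 and SRRM2, with 1 tested and none passing. The hnRNP list had events in HNRNPA2B1, HNRNPLL, HNRNPU and PTBP1, all under the minimum. HNRNPA2B1, also in the m6A list, had 56 inclusion and 12 skipping counts in WT and 2 skipping counts in OE.

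No event was tested in the exosome core (EXOSC2), other splicing regulators (CLK3), nonsense-mediated decay (ATF4, RBM8A), kinase signalling (RPS6KB2), apoptosis (BAX), snoRNA hosts (GAS5, SNHG5, SNHG17), histones (H2AFY) or proteasome subunits (PSMD2, PSMD4), which had listed events below the minimum. Mitochondrially encoded genes had peaks in 3 genes in WT, from 2 peaks, and in 10 in OE, all under 1 peak of 3651 bases. Abundant short noncoding RNAs had RMRP alone. Exosome cofactors, SR proteins, colorectal cancer drivers, snoRNA genes and markers of other cell types had no peak and no event, 5 of the 21 lists.

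The last comparison set peak genes beside splicing events. DEAF1, with a WT peak, was the 1 peak gene with a tested event, a skipped exon on chromosome 11 (651162 to 651407) with 1 inclusion count of 30 in OE and 0 of 37 in WT. EEF1A1 had 2 retained-intron events under the minimum. None of the 8 genes with a passing event had a peak (Fisher's exact p = 1 over 25 tested genes), and with so few genes an association was not detectable.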

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

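The tests in this part were chosen only after the results were seen. IP over input tags at shared summits differed between the genotypes in 6 of 11 testable peaks by an exact test at the library totals, with Benjamini-Hochberg adjustment, all lower in OE. WT over OE enrichment was 12.6 at SAE1P1, 4.87 at SAE1 exon 1, 14.1 at exon 3, 4.49 at exon 7 and 4.24 at exon 9. It was 12.8 at a peak outside genes on chromosome 12 (66057457 to 66057825), with 197 WT and 147 OE tags. The test compares these libraries, not the conditions, and input values were as low as 1 tag. At SAE1P1 the input held 17 tags in WT and 122 in OE.

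The signal over SAE1 and SAE1P1 was weighed further. Reads from 1 source split between gene and pseudogene could be neither excluded nor supported: the OE over WT tag ratio at SAE1P1, 0.903, lay within 0.712 to 0.996 over the 8 exons but outside 0.951 to 0.996 over the 6 exons with at least 100 WT tags, and 3 of 7 unrelated peaks lay in the wider range too. Molecules that hold the coding sequence without its 3' UTR, such as a construct or an amplicon, may also account for it, since peaks covered 155 of 940 bases of the 3' UTR, under 1 extension length of 226 bases in WT or 237 in OE. Reads from SAE1P1, annotated over 1024 bases against 1041 coding bases in SAE1-201, could leave the same gap. The covered length therefore does not separate these sources. More SAE1 RNA bound in the overexpressing cells would raise depth-scaled tags in OE, whereas 9 of 9 summits were lower. With 1 library per group this biological explanation cannot be told apart from a difference between the libraries. The sequence identity of SAE1 and SAE1P1 was not analysed here.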

How the results depend on the processing

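Of 49 alternatives over 14 results, 23 kept the result, 23 moved it and 3 turned its direction; for class medians, kept means within the quartiles of the main values. Of these alternatives 23, those with single values, the stratified test, the authors' inclusion difference, the q threshold, summits, the lists without SAE1 and unscaled tags, were chosen only after the data were seen. The count of 9 splicing calls was 15 with no minimum, 2 with a minimum of 20, 1 by the authors' FDR, 0 after scaling by form length, 0 with first values alone, 1 with second values alone and 1 in the test stratified by value. Fewer events entered at the minimum of 20 and with single values. Scaling by form length cut inclusion counts of the 9 calls from 125 to 13, by 1 factor per event in both genotypes. With so few counts left, rounding to whole counts changed the odds ratios too. This setting therefore cannot tell a lost difference from lost counts. The stratified test could reach an unadjusted p under 0.05 in 4 of the 9. The cause of the other changes was not tested. The share of events higher in OE, 78.1%, was 33.3% with first values alone and 60% with second values alone. The median inclusion difference turned for 5' sites, from 0.48 to -12.9 points at the minimum of 20 (1 event) and -7.72 with first values (2 events), and for skipped exons, from 5.54 to -12.6 with second values (2 events). For retained introns it went from 14 to 0 with first values, where 1 of 5 events was lower and none higher, 3.64 with second values and 3.03 at the minimum of 20. Causes were not tested. With no minimum the medians were 79.9 for 3' sites, 44.4 for 5' sites, 84.8 for retained introns and 58.9 for skipped exons. From differences in the authors' deposited table they were 0.5 for 3' sites, 41.5 for 5' sites, 42.7 for retained introns and 0.9 for skipped exons, which stood at 1.28 at the minimum of 20. Shared OE peaks went from 53.3% to 33.3% without SAE1 and SAE1P1, by construction. By summit position 2 peak classes differed between the lists, introns and the mitochondrial genome, and this alternative changed both the unit counted and the class of some peaks. The median WT fold was 19 among shared peaks, against 3.85 in all. Tags at SAE1 stood at 0.959 times WT in OE when not scaled, against 0.315 after depth scaling. The annotation alternative coincided with the main setting and was not run. No paired analysis was possible because each group had 1 library. Splicing rested on a median of 3 counts per event in each genotype.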

Other observations

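The tests in this part were chosen only after the results were seen. Retained-intron counts differed between the first and second value of each genotype. Inclusion made up 16.3% of WT junction counts in the first value (14.3 to 18.5) and 52.8% in the second (48.4 to 57.3), and 34.4% (28.9 to 40.2) and 84.8% (82.4 to 86.9) in OE. A few genes with most of the counts do not account for it: without the 10 events with the most counts, which took 20.7% of them, the smaller difference was still 33.3 percentage points. The pattern is consistent with values from libraries of different kinds, such as input and IP, not replicates, for retained introns, since the smaller difference within a genotype, 36.5 points, exceeded both differences between genotypes, 18.1 and 31.9 points. Other classes did not all go the same way: inclusion at 3' sites rose from 8.27% to 19.4% in WT and from 13.3% to 75% in OE, but 5' sites fell from 71.3% to 54% and from 81% to 80.4%, skipped exons went from 58.3% to 34% in WT and from 64.7% to 73.1% in OE, and mutually exclusive exons from 72.2% to 31.4% and from 33.3% to 36.5%. Which value is which library stays open, and no biological explanation was tested. The reading as libraries of different kinds assumes the same order in both genotypes, which no source gave. Over all events the first value held more counts in WT (3016 against 817) and the second in OE (1519 against 913). By the peak headers the IP library was the deeper one in both genotypes, so a common order was not established.

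Peaks outside genes and on scaffolds numbered 29 in WT and 12 in OE. Scaffolds left out, 13 of 21 WT peaks (61.9%, 38.4 to 81.9) and 4 of 11 OE peaks (share 0.364, 10.9% to 69.2%) lay in the widest gene-free interval of their chromosome. Over all chromosomes these intervals made up 9.78% of the length between genes. The WT share lay above that beyond counting error, so WT peaks outside genes gathered in these gene-free intervals. Many of them were on chromosome 1, where the widest one made up 20.1%, still below the lower bound for WT. For OE this was not shown, since its lower bound of 10.9% lay close to 9.78%. Most OE peaks concerned were neighbours on chromosome 16 (46387773 to 46390772), where the widest one made up 27.2%. The bounds treat peaks as independent, which neighbours are not. Whether repeated sequence around centromeres gave most peaks outside genes stayed open, since the counting intervals of both lists span a share of 0.5 and repeats were not analysed here. Weak peaks in shallow libraries stayed open too: at q under 0.05 there were 7 such WT peaks and 1 OE peak, a ratio of 7 with an interval of 0.899 to 315. No biological explanation was tested.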
